A study of Arabidopsis thaliana with 10 samples.

How the data were processed

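The samples were 3-day-old seedlings of 5 Arabidopsis thaliana genotypes, kept in darkness at 22 °C for 3 days and collected without roots, with 2 biological replicates per genotype and 10 samples in all. Polyadenylated RNA was sequenced from directional libraries as paired 150 nt reads. The submitters name TAIR10 and BWA 0.7.7; the counting tool, its strand setting and the gene lengths are not given in the sources used here. The deposited table gives RPKM, reads scaled to gene length and to the number of mapped reads by the authors, in 5 columns with 1 value per gene and genotype. Between 48.3% and 48.7% of the values above 0 carry a digit more than the others, and 95.0% to 95.8% of those end in 5, as the mean of 2 rounded numbers does, so each value was taken as the authors' mean of 2 samples. Depth per sample is unknown and no interval was computed.

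The tests set before the data were examined were limma on log2(RPKM + 1) and camera on gene lists. They could not be run, because they need values per sample. The effect size set as an alternative, an absolute log2 difference of 1 or more on log2(RPKM + 1), became the rule, with genes kept if they reached an RPKM of 1 in at least 1 column, 18581 of 33559. Comparisons were each mutant against Col-0, pifq ein3 eil1 against pifq and against ein3 eil1, and the interaction on the log2 scale. Symbols came from the reference gene table, in which 32817 identifiers were found and 742 were not. The description columns of the deposited table were not used, because 12.6% of 16824 descriptions shared a word of at least 4 letters with the gene product of their own line, against 2.03% after shuffling. This raised a doubt whether the RPKM values belong to the identifiers of their lines. The low EIN3, EIL1 and PIF3 values in the mutants of these genes are evidence that they do. Lists fixed by identifier also moved together in pifq, with 14 of 17 PIF-induced genes lower and 30 of 47 photosystem genes higher. Neither list had a member past the threshold the other way. For the genes of these lists, this argues against a general mismatch. Chromosome positions were not used here.

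The 18 gene lists were fixed before the data were examined: mutated genes, apical hook and auxin transport, ethylene signalling and response, ethylene biosynthesis, PIF-induced shade and growth genes, auxin-responsive genes, gibberellin and brassinosteroid, cell wall loosening, photosystem with light harvesting and Rubisco, tetrapyrrole biosynthesis, light signalling regulators, flavonoid biosynthesis, jasmonate and defence, heat shock, low oxygen, root markers, seed storage with late embryogenesis, and reference genes. A list's median was placed among 10000 random lists whose members were drawn from the 200 genes nearest in mean expression. Members were drawn independently, so genes of a list that vary together were not allowed for, and small shifts can reach extreme percentiles. A percentile is therefore a description and not a test, and no correction was made for the number of lists and comparisons. Phosphate starvation, dehydration and light-induced lists were added after seeing the data.

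Named genes followed a rule also set beforehand: the mutated genes, the 5 largest differences each way per comparison among genes past the threshold with a symbol and an RPKM of 10 or more in the higher genotype, up to 4 members per list (where none passed, the 2 most highly expressed), and the 8 genes lower in both pifq and ein3 eil1 with the largest smaller difference. The condition that replicates not overlap could not be applied. A further member was named where a count was 5 or fewer, chosen after its values were seen. An exception was made after the values were seen: genes under 0.001 RPKM in a compared column, and 34 genes listed at 0 in some column and at 10 RPKM or more in another, were not named. It left out PDF2.5 and CLE1, lower in both, which are listed at 0 in every genotype but Col-0.

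Overlaps were set beside the number that independent lists would share and beside 100 simulations of genotypes without any difference that share Col-0, with the noise taken from the difference between pifq ein3 eil1 and pifq, whole or from its median absolute deviation. Alternatives were pseudocounts of 0.1 and 0.5 in place of 1, no filter, an RPKM minimum of 5, median-of-ratios scaling, quantile normalization, a log2 difference of 2 and leaving out genes listed at 0. The procedure was tested on simulated data with 200 genes made different by 1.5-fold to 4-fold and noise of 0.2 on the log2 scale: of 50 genes at each size, 46 to 50 were recovered at 3-fold and 4-fold and 1 to 27 at 1.5-fold and 2-fold. Between 1 and 4 unchanged genes passed. The noise was set per column and not taken from the data, and only genes at 10 RPKM or more were changed. Between the closest genotypes, pifq ein3 eil1 and pifq, the standard deviation was 0.43 for such genes, real differences included. The recovery therefore gives no error rate for the data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.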

Results

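The study measured transcript levels in 3-day-old Arabidopsis thaliana seedlings of 5 genotypes, grown in darkness and harvested without roots. Dark-grown seedlings carry an apical hook, the bend at the top of the hypocotyl that shields the shoot tip, and the comparisons address how transcription factors of the dark-grown state and of ethylene signalling bear on the genes behind it. Col-0 was the wild type. The hls1 mutant lacks HOOKLESS1, which is needed for hook formation. The pifq mutant lacks the PHYTOCHROME INTERACTING FACTORs PIF1, PIF3, PIF4 and PIF5, bHLH factors that keep seedlings in the dark-grown state. The ein3 eil1 mutant lacks EIN3 and EIL1, the main transcription factors of the ethylene response, and pifq ein3 eil1 combines both sets of mutations. Each genotype had 2 biological replicates, 10 samples in all, and the deposited table holds 1 RPKM value per gene and genotype, which is the authors' mean. The spread between replicates is therefore not visible and no difference was tested: a gene is called higher or lower where log2(RPKM + 1) differed by 1 or more, a 2-fold difference in RPKM + 1. Sequencing depth is unknown. Of 33559 genes listed, 18581 reached an RPKM of 1 in at least 1 genotype and were compared. The RPKM columns summed to 862572 in Col-0, 834468 in hls1, 912075 in pifq, 735471 in ein3 eil1 and 837598 in pifq ein3 eil1. Nuclear ribosomal RNA made up 4.27%, 2.40%, 1.28%, 4.43% and 4.52% of these sums in the same order. The median log2 difference from Col-0 over all genes was 0.04 in hls1, -0.05 in pifq, -0.29 in ein3 eil1 and -0.17 in pifq ein3 eil1, so list medians in the last pair are also given relative to it.

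The mutated genes were examined first, and they bear on whether the values belong to the gene identifiers of the table, since its gene descriptions mostly do not match them. EIN3, EIL1 and PIF3, low in their own mutants, are evidence that they do. PIF1 and PIF4 were not low in pifq, and PIF5 in pifq ein3 eil1 was under the threshold. HLS1 in hls1, at a log2 difference of -0.74, was under it too, so no mutated gene clearly marks the hls1 values. Genes without a mutation could not be checked in this way. The PIF-induced and photosystem lists moved together in pifq, as given below, which argues against a general mismatch of identifiers. EIN3 (AT3G20770) stood at 84.0 RPKM in Col-0, 17.9 in ein3 eil1 and 13.3 in pifq ein3 eil1, and EIL1 (AT2G27050) at 44.4, 10.8 and 10.7. PIF3 (AT1G09530) stood at 35.1 RPKM in Col-0, 5.61 in pifq and 2.35 in pifq ein3 eil1, and was also lower, at 12.7, in ein3 eil1. PIF5 (AT3G59060) stood at 4.34 RPKM in Col-0, 16.02 in hls1, 1.60 in pifq and 2.31 in pifq ein3 eil1; its log2 difference in pifq was -1.04, or -0.98 after median-of-ratios scaling. PIF1 (AT2G20180) was at 19.0 RPKM in Col-0 and 18.18 in pifq, and PIF4 (AT2G43010) at 4.36 and 8.69, so the transcripts of these 2 genes were not lower in pifq; a value for the whole gene does not separate intact from truncated transcripts. In pifq ein3 eil1, PIF1 was at 11.8 RPKM, and PIF4 was higher than in Col-0, at 11.6, a log2 difference of 1.24. PIF4 was also higher in hls1, at 9.81, a difference of 1.01, or 0.96 and under the threshold after scaling, and in ein3 eil1 at 8.22 it differed by 0.78, or 1.08 and past the threshold after scaling. HLS1 (AT4G37580) stood at 11.2 RPKM in Col-0, 6.28 in hls1, 7.16 in pifq, 2.84 in ein3 eil1 and 3.04 in pifq ein3 eil1. Its log2 difference from Col-0 was -0.74 in hls1 and -0.58 in pifq, under the threshold, and -1.66 in ein3 eil1 and -1.59 in pifq ein3 eil1. Against pifq, HLS1 in pifq ein3 eil1 differed by -1.01, which was -0.90 and under the threshold after scaling. Against ein3 eil1 the difference was 0.07, or -0.04 after scaling, and the interaction of both sets of mutations was 0.65.

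**Figure D1:**
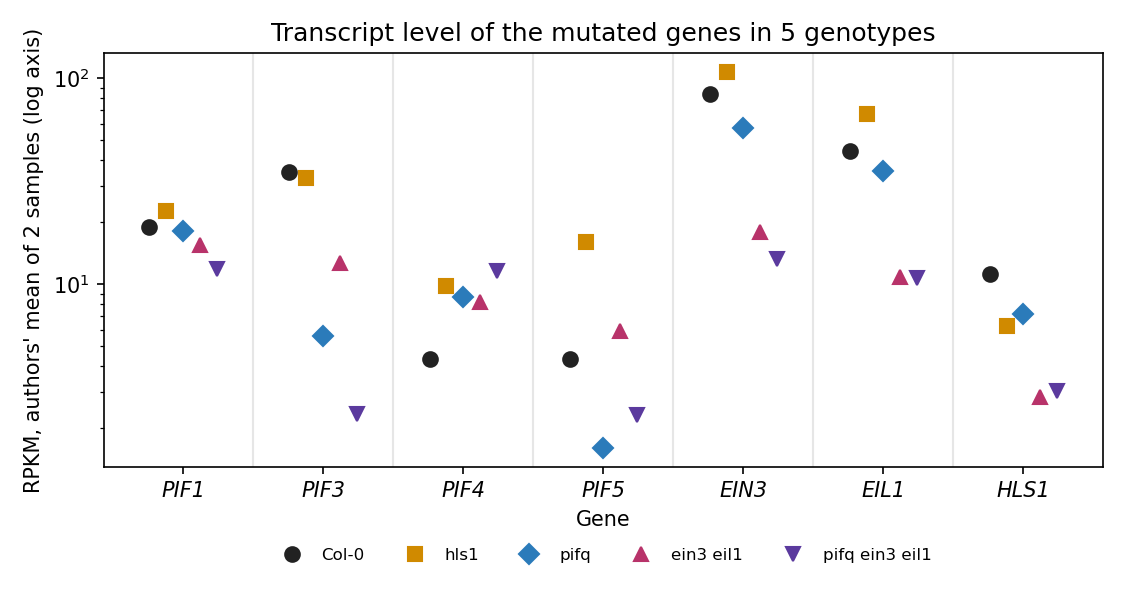
Transcript level of the 7 mutated genes in RPKM on a log axis, with 1 point per genotype, each the authors' mean of 2 samples, drawn without error bars because the table gives none. EIN3 and EIL1 are lowest in ein3 eil1 and pifq ein3 eil1, at 10.7 to 17.9 RPKM, and HLS1 is at 2.84 and 3.04 there against 11.2 in Col-0.

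In hls1, 632 genes were higher and 744 lower than in Col-0. Among the lowest relative to Col-0 was PORA (AT5G54190), a protochlorophyllide oxidoreductase that accumulates in darkness, at 44.5 RPKM against 2089, and the growth-regulating factor gene GRF7 (AT5G53660), at 0.824 RPKM against 108. CEL2 (AT1G02800) stood at 1.38 RPKM against 53.6, the bHLH gene HEC2 (AT3G50330) at 1.87 RPKM against 51.5 and DAA1 (AT1G64110) at 2.03 RPKM against 49.9. Among the highest was ACO4 (AT1G05010), an ACC oxidase of the last step of ethylene synthesis, at 885 RPKM against 41.6. ELI3-1 (AT4G37980) stood at 15.6 RPKM against 0.936, the auxin transporter gene ABCB21 (AT3G62150) at 21.4 RPKM against 2.97, the nitrate transporter gene NRT1.7 (AT1G69870) at 21.8 RPKM against 3.16 and the pseudogene SADHU3-2 (AT3G42658) at 30.7 RPKM against 3.78.

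Of 27 tetrapyrrole biosynthesis genes, 3 were lower in hls1 and none was higher. These were PORA, PORB at 145 RPKM against 1481 and PORC at 16.1 RPKM against 39.8, and the list median of -0.40 lay at the 0.055 percentile of random lists of matched expression. The 47 photosystem, light harvesting and Rubisco genes had a median of 0.12, with 1 higher member, LHCB1.5, at 929 RPKM against 407. Among 16 hook and auxin transport genes, 1 passed the threshold, SAUR17, at 5.01 RPKM against 73.0. Of 17 PIF-induced shade and growth genes, 4 were higher and 1 lower: ST2A stood at 226 RPKM against 58.7, PIL1 at 208 RPKM against 54.9, HFR1 at 167 RPKM against 48.0 and CKX5 at 28.5 RPKM against 13.6, whereas PAR1 stood at 46.5 RPKM against 120.1; after scaling 3 were higher. Of 14 ethylene biosynthesis genes, ACO4 and ACS8 were higher and ACS4 lower. Of 18 ethylene signalling and response genes, 1 passed the threshold, ORA59, higher at 1.55 RPKM against 0.0512, and the list median was 0.41. Of 24 cell wall loosening genes, 4 were higher, including EXPA1 at 461 RPKM against 102 and XTH23 at 61.5 RPKM against 16.7, and 2 lower, EXPA4 at 15.2 RPKM against 72.1 and XTH5 at 23.3 RPKM against 66.4. After scaling, 2 were higher. Of 22 gibberellin and brassinosteroid genes, GA2OX2 and BES1 were higher and GA2OX6 and GA2OX8 lower. MYB111 and FLS1 were the lower members of 10 flavonoid genes, and AOS, at 30.4 RPKM against 4.78, was the 1 higher member of 9 jasmonate and defence genes. GNC was lower among 17 light signalling regulators, SAUR14 higher among 29 auxin-responsive genes, PDC1 higher among 9 low-oxygen genes, and HSP22.0 and HSP18.2 lower among 7 heat shock genes. After scaling 1 photosystem gene and 1 auxin-responsive gene were lower too. Of 9 measured root markers, PRP3 was higher and THAS1 lower. Beside the tetrapyrrole list, the medians relative to all genes lay under the 1 percentile of random lists for the flavonoid (-0.65) list and above the 99 percentile for the ethylene response (0.36), cell wall (0.34) and photosystem (0.07) lists.

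In pifq, 629 genes were higher and 1156 lower than in Col-0. Genes for light-harvesting chlorophyll-binding proteins led those that were higher. LHCB1.4 (AT2G34430) stood at 1875 RPKM against 61.3, LHCB1.1 (AT1G29920) at 3468 RPKM against 173, LHCB1.5 (AT2G34420) at 3694 RPKM against 407 and LHCB1.2 (AT1G29910) at 2878 RPKM against 323. These copies are nearly identical in sequence, so the division of reads among them is uncertain. QQS (AT3G30720), a regulator of starch content, stood at 11.1 RPKM against 0.330. The lowest relative to Col-0 were the B-box gene bbx23 (AT4G10240) at 0.909 RPKM against 114, FLP1 (AT4G31380) at 1.49 RPKM against 105, XTH15 (AT4G14130), a xyloglucan endotransglucosylase gene, at 48.2 RPKM against 1922, and the early light-induced genes ELIP1 (AT3G22840) at 10.3 RPKM against 381 and ELIP2 (AT4G14690) at 14.9 RPKM against 469.

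Of the 47 photosystem, light harvesting and Rubisco genes, 30 were higher in pifq and none was lower, with a median log2 difference of 1.29 that lay above all 10000 random lists. Of 27 tetrapyrrole genes, 5 were higher, led by GUN4 at 374 RPKM against 147, CRD1 at 1112 RPKM against 449.9 and CAO at 99.96 RPKM against 42.8, and PORA was lower at 403 RPKM against 2089. Of 17 PIF-induced shade and growth genes, 14 were lower and none was higher, with a median of -1.99 below all random lists. Besides XTH15, PIL1 stood at 1.08 RPKM against 54.9, HFR1 at 1.42 RPKM against 48.0 and ATHB2 at 5.95 RPKM against 77.7. Of 29 auxin-responsive genes, 18 were lower, among them IAA29 at 2.26 RPKM against 26.5, SAUR24 at 4.61 RPKM against 34.5, IAA19 at 56.8 RPKM against 319 and SAUR23 at 26.7 RPKM against 145, and 1 was higher, SAUR14, at 125 RPKM against 41.0. SAUR19 to SAUR24 are close paralogues, again with an uncertain division of reads. Of 16 hook and auxin transport genes, 4 were lower: SAUR17 at 11.0 RPKM against 73.0, the kinase genes WAG1 at 2.67 RPKM against 12.6 and WAG2 at 8.75 RPKM against 27.1, and IAA3 at 37.0 RPKM against 103. Of 14 ethylene biosynthesis genes, 5 were lower, including ACO5 at 5.64 RPKM against 137 and ACS5 at 0.716 RPKM against 17.7, and ACO4 was higher at 104 RPKM against 41.6. EDF3, HCHIB and RAV1 were the lower members of 18 ethylene signalling and response genes. Cell wall loosening genes went both ways, with 4 higher, such as EXPA10 at 83.7 RPKM against 17.0, and 7 lower, such as XTH18 at 25.3 RPKM against 182 and XTH30 at 21.4 RPKM against 96.0; reads of XTH17 and XTH18 are hard to tell apart. Of 9 low-oxygen genes, 4 were higher, led by ADH1 at 386 RPKM against 142, or 6 after scaling. HYH, HY5 and BBX20 were lower among 17 light signalling regulators, and 5 of 10 flavonoid genes were lower, led by MYB75 at 0.450 RPKM against 8.67. GA2OX8, ROT3 and BR6OX2 were lower among 22 gibberellin and brassinosteroid genes. Of 9 jasmonate and defence genes, LOX2 and AOC1 were higher and MYC2 lower, and HSP22.0 was lower among 7 heat shock genes. Root-associated transcripts differed too: 5 of 9 measured root markers were lower, including the aquaporin gene TIP2;3 at 1.33 RPKM against 27.3 and the endodermal gene CASP1 at 15.4 RPKM against 83.8. The seedlings were collected without roots, and a difference in remaining root tissue was not tested in this or any other comparison. Scaling left 2 lower ethylene response genes and 17 lower auxin-responsive genes, and made 32 photosystem genes higher. Relative to all genes, other list medians under the 1 percentile of random lists were those of the mutated genes (-0.50), ethylene response (-0.37), ethylene biosynthesis (-0.41), auxin-responsive (-1.20), cell wall (-0.45), flavonoid (-0.94) and root marker (-1.15) lists. Above the 99 percentile, besides the photosystem list, were the tetrapyrrole (0.60) and low-oxygen (1.03) lists.

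**Figure D2:**
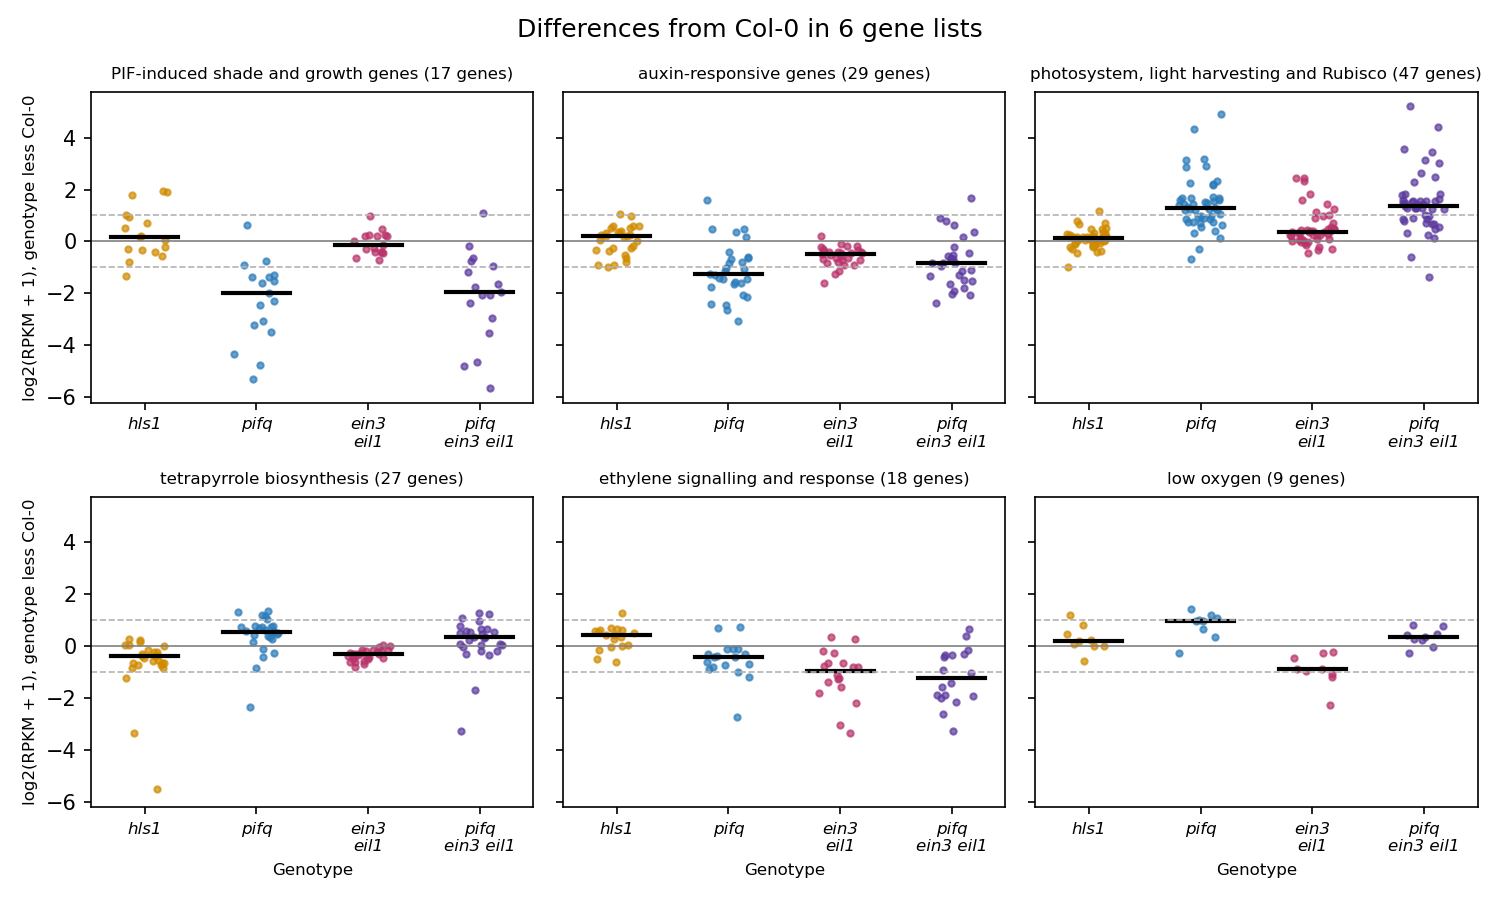
Differences in log2(RPKM + 1) from Col-0 for the members of 6 gene lists, with 1 point per gene, 1 position per mutant genotype, black bars at the list medians and dashed lines at the threshold of 1. The photosystem list has medians of 1.29 in pifq and 0.37 in ein3 eil1, and the list of PIF-induced genes has medians of -1.99 and -0.15.

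In ein3 eil1, 303 genes were higher and 467 lower than in Col-0, 39.4% of them higher; after median-of-ratios scaling, which removed the shift of -0.29 in the median of all genes, 445 were higher and 203 lower, or 68.7% higher. At a log2 difference of 2 or more, 93 were higher and 42 lower. Genes lower by the most were AZI1 (AT4G12470), a lipid transfer protein gene, at 7.46 RPKM against 206, EBF2 (AT5G25350), an F-box gene whose product targets EIN3 for degradation, at 7.44 RPKM against 86.1, the fatty acid desaturase gene ADS1 (AT1G06080) at 4.67 RPKM against 49.7, the ethylene receptor gene ETR2 (AT3G23150) at 2.37 RPKM against 26.7 and FTM1 (AT1G43800) at 68.3 RPKM against 393. Those higher by the most had low values in Col-0. LEA7 (AT1G52690), RAB18 (AT5G66400) and LTI30 (AT3G50970), which respond to dehydration and abscisic acid, stood at 11.6 RPKM against 0.208, 10.7 RPKM against 0.485 and 14.9 RPKM against 1.66. AIR1 (AT4G12550) stood at 36.0 RPKM against 3.15 and CYP81F4 (AT4G37410), of indole glucosinolate synthesis, at 23.57 RPKM against 2.09. Beside these, 3 of 4 measured seed storage and late embryogenesis genes were higher, CRU1 at 3.42 RPKM against 0.152, EM1 at 2.95 RPKM against 0.142 and CRU3 at 1.87 RPKM against 0.0628. In Col-0 these seed genes were far under the filter of 1 RPKM in any genotype, so they could pass it through ein3 eil1 itself. The count and the medians of this list in comparisons with ein3 eil1 are therefore not independent of the filter.

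Of 18 ethylene signalling and response genes, 9 were lower in ein3 eil1, or 6 after scaling, and none was higher. The list median of -0.97, or -0.68 relative to all genes, lay below all random lists, and its lower members included ARL at 21.6 RPKM against 103 and EBF1 at 9.48 RPKM against 36.1. Of 16 hook and auxin transport genes, 4 were lower, or 3 after scaling: SAUR17 at 12.3 RPKM against 73.0, HLS1, WAG1 at 4.18 RPKM against 12.6 and WAG2 at 11.3 RPKM against 27.1. The 47 photosystem, light harvesting and Rubisco genes included 9 that were higher, or 12 after scaling, and none that was lower. Their median of 0.37, or 0.65 relative to all genes, lay above all random lists, with LHCB1.1 at 954 RPKM against 173 and LHCB1.5 at 2053 RPKM against 407. Plastid-encoded transcripts made up 7.05% of the summed RPKM in ein3 eil1 and 2.72% in Col-0. Mitochondrial transcripts were higher as well, at a sum of 2058 RPKM against 795. The libraries were made from polyadenylated RNA, and a difference in that selection was not tested. No PIF-induced gene of 17 passed the threshold, with 1 higher after scaling; XTH15 was at 1219 RPKM against 1922 and IAA19 was at 238 RPKM against 319, and the list median relative to all genes was 0.14, at the 98.7 percentile. No tetrapyrrole gene of 27 did; PORA was at 1411 RPKM against 2089 and PORB was at 1091 RPKM against 1481. Of 9 low-oxygen genes, 3 were lower, HB1 at 106 RPKM against 511, HRA1 at 31.5 RPKM against 73.2 and ADH1 at 66.5 RPKM against 142 and 1 was lower after scaling. Of 14 ethylene biosynthesis genes, ACO5 was lower at 55.2 RPKM against 137 and ACS8 higher at 9.30 RPKM against 3.97; after scaling no member was lower. SAUR24, SAUR10 and SAUR15 were lower among 29 auxin-responsive genes, with 1 lower after scaling, and EXPB1, XTH18 and XTH17 lower and EXPA2 higher among 24 cell wall loosening genes, with 1 lower after scaling. HY5, FLS1 and HSP22.0 were the lower members of the light signalling, flavonoid and heat shock lists, and no member of these lists was lower after scaling, while 1 heat shock gene was higher. In the gibberellin and brassinosteroid list no member passed, with 1 higher after scaling; CPD was at 88.9 RPKM against 99.4 and BES1 was at 30.6 RPKM against 46.1. In the jasmonate and defence list none passed either; MYC2 was at 24.0 RPKM against 24.0 and OPR3 was at 13.3 RPKM against 13.6, and the list median relative to all genes was 0.40, at the 99.7 percentile. Of 9 measured root markers, PRP3, THAS1 and MRN1 were higher, THAS1 at 29.2 RPKM against 8.62, and a difference in remaining root tissue was not tested. List medians relative to all genes also lay under the 1 percentile in the mutated genes (-1.12), auxin-responsive (-0.21), flavonoid (-0.35) and low-oxygen (-0.61) lists. They lay above the 99 percentile in the root marker (0.92) and seed storage (1.90) lists too, the latter with the limit of the filter given above.

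In pifq ein3 eil1, 708 genes were higher and 1122 lower than in Col-0, 38.7% of them higher, against 915 and 840, or 52.1% higher, after scaling. The photosystem list had 31 higher members of 47, with a median of 1.38, or 1.55 relative to all genes, and RBCS2B was its 1 lower member; LHCB1.4 stood at 2316 RPKM against 61.3 and LHCB1.1 at 3696 RPKM against 173. The phosphatase genes PS2 (AT1G73010) at 52.9 RPKM against 1.55 and PEPC1 (AT1G17710) at 14.7 RPKM against 0.0328 and AIR1 at 69.1 RPKM against 3.15 were also among the highest. Lowest relative to Col-0 were bbx23 at 1.02 RPKM against 114, XTH15 at 36.7 RPKM against 1922, the homeobox gene HB52 (AT5G53980) at 2.13 RPKM against 154, AZI1 at 4.15 RPKM against 206 and ELIP1 at 9.68 RPKM against 381. Of 17 PIF-induced genes, 12 were lower and 1 higher (YUC9), of 29 auxin-responsive genes 12 were lower and 1 higher (SAUR14), and of 18 ethylene signalling and response genes 10 were lower and none was higher. The lower members of the hook and auxin transport list were SAUR17 at 4.44 RPKM against 73.0, WAG1 at 1.23 RPKM against 12.6, WAG2 at 3.66 RPKM against 27.1 and HLS1. Among ethylene biosynthesis genes, those lower included ACO5 at 3.52 RPKM against 137, ACS5 at 0.869 RPKM against 17.7 and ACS2, and those higher were ACO4 at 140.0 RPKM against 41.6 and ACS11. PORA at 213 RPKM against 2089 and PORB at 459 RPKM against 1481 were lower, and CAO, HEMA1 and GUN4 higher, among 27 tetrapyrrole genes. Of 24 cell wall loosening genes, 5 were higher and 8 lower. No low-oxygen gene of 9 passed the threshold; HB1 was at 869 RPKM against 511 and ADH1 was at 182 RPKM against 142, and the list median relative to all genes was 0.52, at the 99.8 percentile. LOX2, AOC1 and AOS were higher and MYC2 lower among 9 jasmonate and defence genes. HY5, BBX20, HYH and GATA2 were among 6 lower light signalling regulators, and MYB75, F3H and CHS were lower among 10 flavonoid genes. GA2OX8 and ROT3 were lower and GA2OX2 higher among 22 gibberellin and brassinosteroid genes, and HSP22.0 was lower and HSP17.6A higher among 7 heat shock genes. TIP2;3, CASP1 and CASP2 were lower and MRN1 and PRP3 higher among the 9 measured root markers. After scaling the lower members numbered 9 in the ethylene response list, 11 in the PIF-induced, 10 in the auxin-responsive and 2 in the flavonoid list. The higher ones numbered 36 in the photosystem, 4 in the tetrapyrrole, 2 in the auxin-responsive and 2 in the heat shock list. Under the 1 percentile, relative to all genes, lay the medians of the mutated genes (-1.42), hook and auxin transport (-0.31), ethylene response (-1.05), PIF-induced (-1.77), auxin-responsive (-0.65), gibberellin and brassinosteroid (-0.30) and flavonoid (-0.67) lists. The photosystem (1.55), tetrapyrrole (0.51) and jasmonate (0.82) lists lay above the 99 percentile besides the low-oxygen list.

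The effect of losing EIN3 and EIL1 where the PIFs were already absent was read from pifq ein3 eil1 against pifq. Of the 7 comparisons it gave the fewest differing genes, 327 higher and 209 lower, 61.0% higher, against 406 and 152, or 72.8% higher, after scaling. The balance turned among genes at 10 RPKM or more in a compared genotype, with 99 higher and 114 lower. EBF2 at 8.07 RPKM against 65.8, AZI1 at 4.15 RPKM against 31.8, the bHLH gene CIB1 (AT4G34530) at 2.16 RPKM against 15.8, EIN3 itself and the abscisic acid receptor gene PYL2 (AT2G26040) at 11.2 RPKM against 46.6 were lower. AIR1 at 69.1 RPKM against 7.42, MLP34 (AT1G70850) at 49.9 RPKM against 6.91, DR4 (AT1G73330) at 24.8 RPKM against 3.65, CYP705A5 (AT5G47990), of triterpene synthesis, at 14.4 RPKM against 2.15 and BCB (AT5G20230) at 22.1 RPKM against 3.83 were higher. Of 18 ethylene signalling and response genes, 6 were lower, or 4 after scaling, with ARL at 22.3 RPKM against 76.8, ETR2 at 5.95 RPKM against 21.2 and EBF1 at 8.90 RPKM against 26.8, and 1 was higher (HCHIB). SAUR17, WAG2 and HLS1 were lower among 16 hook and auxin transport genes and 1 was lower after scaling. No photosystem gene passed the threshold; LHCB1.3 was at 18629 RPKM against 24893 and RBCS1A was at 9579.5 RPKM against 11028, and the list median relative to all genes was 0.14, at the 99.8 percentile of random lists. The same held for the tetrapyrrole list, where PORA was at 213 RPKM against 403 and PORB was at 459 RPKM against 829, the auxin-responsive list, where IAA7 was at 173 RPKM against 146 and IAA2 was at 140.3 RPKM against 130.3, the PIF-induced list, where XTH15 was at 36.7 RPKM against 48.2 and IAA19 was at 61.2 RPKM against 56.8, and the gibberellin and brassinosteroid list, where CPD was at 60.4 RPKM against 65.6 and BES1 was at 42.3 RPKM against 78.8. Of the 29 auxin-responsive genes 26 were above 0, with a median relative to all genes of 0.35 above all random lists, and that of the PIF-induced list was 0.29 at the 99.9 percentile. After scaling 1 member of each of these 2 lists was higher. Among single members past the threshold, ACS8, MYB75, LOX2 and EXPA2 were higher in their lists, and GLK1 was lower at 15.1 RPKM against 34.6, as was ADH1 at 182 RPKM against 386, which did not pass after scaling. HSP17.4 and HSP17.6A were the higher heat shock genes. Of 9 root markers 4 were higher, among them MRN1 at 6.86 RPKM against 0.358 and THAS1 at 6.23 RPKM against 1.15. Remaining root tissue was not separated from an effect of losing EIN3 and EIL1. After scaling 5 root markers and 2 ethylene biosynthesis genes were higher. Further list medians above the 99 percentile, relative to all genes, were those of the cell wall (0.16), heat shock (0.69) and root marker (1.06) lists. Only that of the mutated genes (-0.87) lay under the 1 percentile.

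The effect of losing the PIFs where EIN3 and EIL1 were absent, pifq ein3 eil1 against ein3 eil1, comprised 750 higher and 741 lower genes, 50.3% higher, against 576 and 920, or 38.5% higher, after scaling, and 106 and 181 at a log2 difference of 2 or more. XTH15 at 36.7 RPKM against 1219, PIL1 at 0.9996 RPKM against 62.7, FLP1 at 2.40 RPKM against 101, HFR1 at 0.971 RPKM against 56.3 and ELIP1 at 9.68 RPKM against 274 were lower. PS2 at 52.9 RPKM against 3.21, ECS1 (AT1G31580) at 41.9 RPKM against 3.13, PEPC1 at 14.7 RPKM against 0.705, the glycerophosphodiester phosphodiesterase gene GDPD6 (AT5G08030) at 10.5 RPKM against 0.285 and the non-symbiotic haemoglobin gene HB1 (AT2G16060) at 869 RPKM against 106 were higher. Of 17 PIF-induced genes, 13 were lower and 1 higher (YUC9). Of 47 photosystem genes, 20 were higher, or 13 after scaling, and RBCS2B was lower. Low-oxygen genes included 5 higher members of 9, or 3 after scaling, with HRA1 at 87.7 RPKM against 31.5. Of 29 auxin-responsive genes, 6 were lower, such as IAA29 at 5.49 RPKM against 31.0, and 3 higher, such as SAUR14 at 134 RPKM against 33.4; after scaling 2 were higher. WAG2, SAUR17 and WAG1 were lower in the hook and auxin transport list, and 4 ethylene biosynthesis genes were higher and 4 lower, with ACO5 at 3.52 RPKM against 55.2 and ACO4 at 140.0 RPKM against 49.9. In the ethylene signalling and response list EDF3 was lower and RAV2 and ETR2 higher; after scaling the balance turned, with 1 higher and 2 lower. HEMA1, CAO and GUN4 were among 5 higher tetrapyrrole genes, and PORA and PORB were lower. GATA2, BBX20 and PHYA were the lower light signalling regulators, or 4 genes after scaling. Of 24 cell wall loosening genes 3 were higher and 6 lower, or 7 after scaling. ROT3 and GA2OX8, MYB75, MYC2 and HSP22.0 were lower in their lists, and LOX2 and, before scaling, HSP18.2 higher. Of 9 root markers 4 were lower and none was higher, and of 4 seed genes EM1, CRU1 and CRU3 were lower. Set among random lists, the medians relative to all genes of the mutated genes (-0.49), hook and auxin transport (-0.38), ethylene biosynthesis (-0.48), PIF-induced (-1.60), auxin-responsive (-0.27), gibberellin and brassinosteroid (-0.38), cell wall (-0.21), flavonoid (-0.41), root marker (-0.53) and seed storage (-1.47) lists lay under the 1 percentile. Those of the photosystem (0.83), tetrapyrrole (0.51), jasmonate (0.48) and low-oxygen (0.96) lists lay above the 99 percentile. The seed storage value is limited by the filter, as in ein3 eil1 against Col-0.

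The genotypes Col-0, pifq, ein3 eil1 and pifq ein3 eil1 form a factorial, and the interaction is the PIF effect without EIN3 and EIL1 less that with them, with 0 for additivity on the log2 scale. It was 1 or more in 622 genes and -1 or less in 279, 69.0% positive, against 412 and 360, or 53.4% positive, after scaling. At a size of 2 or more the balance turned, with 70 positive and 86 negative. LHCB1.1 had an interaction of -2.37 and LHCB1.4 of -2.15, and 8 of 47 photosystem genes were at -1 or less, or 9 after scaling, and none at 1 or more. LHCB1.1 was above its Col-0 level of 173 RPKM in both, at 3468 in pifq and 954 in ein3 eil1, and at 3696 in pifq ein3 eil1. LEA7 had an interaction of -3.52, RAB18 of -3.49 and LTI30 of -2.48, and EM1, CRU1 and CRU3 were also at -1 or less. The most positive were RTFL12 (AT4G13395) at 2.70, XTH7 (AT4G37800) at 2.56, the calmodulin-like gene TCH3 (AT2G41100) at 2.40, CYS2 (AT2G31980) at 2.28 and SAUR24 (AT5G18080) at 2.26. Of 29 auxin-responsive genes 12 were at 1 or more, or 8 after scaling, and none at -1 or less, with SAUR15 at 1.88, SAUR10 at 1.71 and SAUR20 at 1.44. SAUR17 and IAA3 in the hook list, EDF3 and ETR2 in the ethylene response list, HYH and HY5 among light signalling regulators, XTH19 and XTH18 among cell wall genes and MYB75, FLS1 and F3H among flavonoid genes were at 1 or more; after scaling, the counts were 1, 2, 1, 1 and 2 in the same order. ACS4, GA2OX8, HSP22.0, HB1 and, before scaling, IAA6 were at 1 or more too, and 1 ethylene biosynthesis gene was at -1 or less after scaling. In the tetrapyrrole, jasmonate and root marker lists no gene passed the threshold, with values of PORA -0.35 and PORB -0.41 in the first, MYC2 0.25 and OPR3 0.05 in the second and PYK10 0.23 and CASP1 0.48 in the last. Of the list medians of the interaction relative to all genes, those of the photosystem (-0.57) and seed storage (-1.89) lists lay under the 1 percentile of random lists. The ethylene response (0.30), auxin-responsive (0.60) and flavonoid (0.60) lists had medians above the 99 percentile. The filter limits the seed storage value here too.

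Genes lower in both pifq and ein3 eil1 than in Col-0 numbered 174, of 1156 and 467, where independent lists of those sizes would share 29.1. Led by the size of the smaller difference, they were AZI1, SAUR17 (AT4G09530), ADS1, CIB1, the fatty acyl reductase gene FAR1 (AT5G22500) at 332 RPKM in Col-0, 28.4 in pifq and 85.3 in ein3 eil1, ST4C (AT1G13430) at 23.59, 2.65 and 5.59, HB52 at 154, 6.93 and 44.5, and CYP96A5 (AT2G21910) at 34.3, 0.312 and 9.44. Of the 174 genes, 62 were also lower in hls1, or 39 of the 94 lower in both after scaling and 40 with genes listed at 0 left out, and 143 in pifq ein3 eil1, again against the same Col-0. In pifq ein3 eil1, 15 of them were lower still than in pifq, 44 lower than in ein3 eil1 and 13 lower than in both; 20 were higher than in pifq and 14 higher than in ein3 eil1. The interaction was 1 or more in 121, a smaller combined difference than the sum, and -1 or less in none. These genes were chosen for a difference of -1 or less in both, and log2(RPKM + 1) cannot fall below 0. A gene with a low Col-0 level therefore cannot reach the sum, and this limit was not separated from the 121. Genes higher in both numbered 76, of 629 and 303, with 10.3 for independent lists. Both comparisons use the same Col-0 values. Simulated genotypes without any difference, set against a shared Col-0, gave 95.8 genes lower in both and 94.4 higher when the noise was the whole difference between pifq ein3 eil1 and pifq, which holds real differences, and 3.84 and 3.44 when it was the central spread of that difference. With another such genotype in the place of hls1, 74.0 and 0.9 genes on average were lower in all 3 with the larger and the smaller noise, so the 62 cannot be separated from the shared column. After scaling, 94 genes were lower in both and 110 higher. Col-0 could not be split, so part of each overlap, and of the positive interactions, may come from the shared column.

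Across all 18581 genes, which are not independent replicates, the PIF effect in the wild-type background correlated with that in the ein3 eil1 background with r = 0.64, and 521 genes were lower and 315 higher in both, where independent lists would share 46.1 and 25.4. The EIN3 EIL1 effect in the wild-type background correlated with that in the pifq background with r = 0.32, with 81 genes lower and 78 higher in both against 5.25 and 5.33. The difference between hls1 and Col-0 correlated with the PIF effect in the ein3 eil1 background with r = 0.06 and with the EIN3 EIL1 effect in the pifq background with r = 0.21. None of these pairs shares a column. Among pairs that share Col-0, r was 0.24 for pifq with ein3 eil1, 0.15 for hls1 with pifq, 0.32 for hls1 with ein3 eil1 and 0.29 for hls1 with pifq ein3 eil1. Simulation without any difference gave 0.50. That value is fixed by sharing 1 column with equal noise, whatever the size of the noise, so no conclusion is drawn from it. The covariance was 0.079, 0.060, 0.093 and 0.113 in the same order, against a simulated 0.094 with the larger noise and 0.048 with the smaller; it lay between these values for all but the last pair. In all, 8 correlations were computed.

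**Figure D3:**
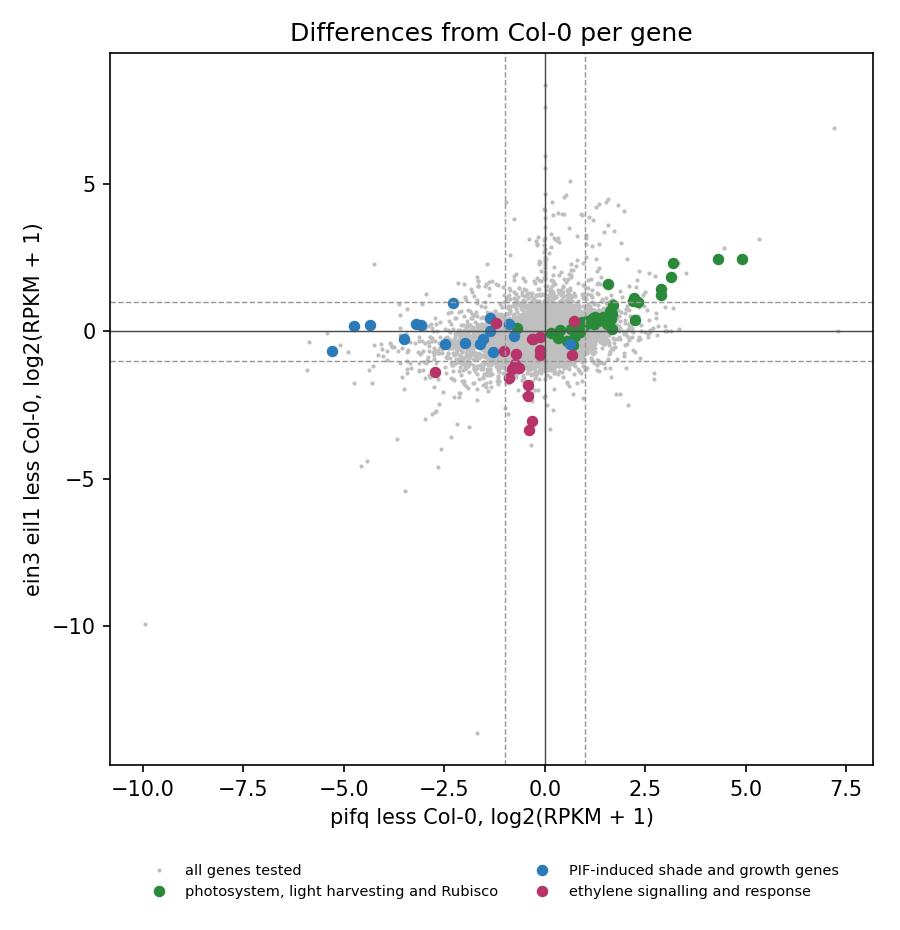
Difference from Col-0 in log2(RPKM + 1) for each of 18581 genes, in pifq on the horizontal axis and in ein3 eil1 on the vertical axis, with dashed lines at the threshold of 1 and the members of 3 gene lists coloured. Photosystem genes have medians of 1.29 and 0.37, PIF-induced genes of -1.99 and -0.15, and ethylene response genes of -0.42 and -0.97.

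The 7 reference genes passed the threshold in none of the 7 comparisons, before or after scaling; in ein3 eil1 EF1A was at 944 RPKM against 1181 and GAPC1 was at 658 RPKM against 705. The 4 measured seed storage and late embryogenesis genes did not pass in hls1, pifq or pifq ein3 eil1 against Col-0, or in pifq ein3 eil1 against pifq, and in pifq CRU1 was at 0.752 RPKM against 0.152 and EM6 was at 0.0907 RPKM against 0.888. Another 9 genes of that list and 5 of 14 root markers stayed under 1 RPKM in every genotype.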

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

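All of the tests in this part were chosen only after the result was seen. The LEA7, RTFL12 and RAB18 transcripts differed from loss of the PIFs in opposite directions in the wild-type and in the ein3 eil1 background. Among genes listed above 0 in these 4 genotypes and at 10 RPKM or more in at least 1, they are 3 of 14 with such opposite effects past the threshold, and the other 11 are plastid-encoded. All 11 were higher in pifq than in Col-0 and lower in pifq ein3 eil1 than in ein3 eil1, as LEA7 and RAB18 were. All plastid-encoded transcripts together summed to 51886 RPKM in ein3 eil1, 23505 in Col-0, 23810 in pifq and 27143 in pifq ein3 eil1. The falls of the 11 were not separated from this high plastid sum of the ein3 eil1 column, nor from a difference in the selection of polyadenylated RNA. Loss of EIN3 and EIL1 had opposite effects on 8 genes. For LEA7 the log2 difference was 1.475 in the wild-type and -2.04 in the ein3 eil1 background, for RAB18 it was 1.36 and -2.13, and for RTFL12 it was -1.41 and 1.29. RPKM in Col-0, pifq, ein3 eil1 and pifq ein3 eil1 was 0.208, 2.36, 11.6 and 2.06 for LEA7, 0.485, 2.81, 10.7 and 1.68 for RAB18, and 47.1, 17.1, 10.8 and 27.9 for RTFL12. The difference between the backgrounds was not tested, since individual samples are not visible in the deposited means.

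PORA and PORB were far lower in hls1, at 44.5 RPKM against 2089 and 145 RPKM against 1481. Light reaching the hls1 seedlings would raise light-induced transcripts, but 10 of them had a median log2 difference of -0.35, with quartiles of -0.65 and 0.36. Of these, 4 were above 0 and 6 below, and none was higher past the threshold. In pifq 4 were higher and 4 lower, so the genes do not move together and their median is a weak measure of light. Less cotyledon tissue would lower abundant cotyledon transcripts, but the photosystem list had a median of 0.12, with quartiles of -0.08 and 0.24. The photosystem values thus argue against less cotyledon tissue, while the light-induced genes give only weak evidence against light. A difference between batches or a mislabelled sample was not tested, because samples are pooled, and an effect of losing HLS1 stays open as untested.

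The median of all genes was lower in ein3 eil1 than in Col-0 by a log2 difference of -0.29. A larger share of the 10 highest nuclear genes accounted for -0.012 of it, which argues against that explanation. A larger share of plastid-encoded RNA, 7.05% of summed RPKM against 2.72%, accounted for -0.066. Lengths were available for 0 of 133 plastid genes, so shares of reads are unknown, and a share of 20.2% in ein3 eil1 would be needed with 2.72% in Col-0, so this explanation cannot be told apart from others. The summed RPKM was also lower in ein3 eil1, at 735471 against 862572, as was that of protein-coding genes, at 643321 against 795638. The median shift thus goes with a lower column total, whose source was not tested. RPKM is scaled to mapped reads, so a difference in depth is divided out unless the authors' normalization departed from that. Such a departure stays open, as do a difference in the selection of polyadenylated RNA and an effect of the mutations.

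Light-harvesting transcripts were higher in ein3 eil1. Reads shared between the LHCB1 copies would leave other members near the median of all genes, but the 42 members outside LHCB1 had a median of 0.62 relative to it, and the summed RPKM of the 5 copies was 11266 against 6185. RNA from pifq mixed into the ein3 eil1 material would give the same implied share in every gene high in pifq. The implied median share was 39.6% over 32 list genes and 10.3% over 17 other genes, with quartiles of 3.90% and 16.7% in the latter, so mixing does not account for the whole pattern. An effect of losing EIN3 and EIL1, and a batch difference, stay open.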

How the results depend on the processing

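The alternatives with a log2 difference of 2 and with genes listed at 0 left out were chosen after seeing the data; the others were set before the data were examined. Of 668 values of 108 results under these alternatives, 637 stayed near the value reported (within 1.5 times for counts, 1.5-fold for log2 values and 0.1 for correlations), 28 moved further and 3 reversed, counting only log2 values of 0.25 or more in size as reversed. Changed genes were scored as totals, so their balance of direction was not scored. Under median-of-ratios scaling the ein3 eil1 total went from 770 to 648, within 1.5 times. Its share of higher genes went from 39.4% to 68.7%, and that in pifq ein3 eil1 from 38.7% to 52.1%. Another 9 values, of results reported at less than 0.25 in size, changed sign, among them HLS1 in pifq ein3 eil1 against ein3 eil1, from 0.07 to -0.04 and -0.03 under both scalings, and PIF1 in pifq, from -0.06 to 0.04 under quantile normalization. The 70 differences named for their size, of 50 genes, kept their direction in the 6 alternatives run for them. They were chosen as the largest in the same data, the smallest being PYL2 at -1.97 in pifq ein3 eil1 against pifq. A change of sign was therefore hardly possible, and no conclusion on robustness is drawn from it. With a pseudocount of 0.1 the genes past the threshold were 2200 in hls1, 2688 in pifq and 1504 in ein3 eil1, 1142 in pifq ein3 eil1 against pifq, 2420 against ein3 eil1 and 1724 for the interaction. It gave 288 genes lower and 211 higher in both pifq and ein3 eil1, 102 of the former lower in hls1, and root marker medians, relative to all genes, of -2.09 in pifq and 1.95 in ein3 eil1. A pseudocount of 0.5 gave 117 genes higher in both. A lower pseudocount widens differences between small values by construction. With an RPKM minimum of 5, the root marker median relative to all genes was -0.43 in hls1, with its sign changed from 0.18, -1.97 in pifq and, reversed from 0.31, -0.22 in pifq ein3 eil1; fewer root markers pass that minimum. Median-of-ratios scaling gave 94 genes lower in both, 39 of them lower in hls1, and quantile normalization gave 102; the difference of PIF1 in ein3 eil1 reversed from -0.28 to 0.046 and 0.047 under these 2, which remove the shift of the all-gene median. A log2 difference of 2 or more, a stricter rule, left 195, 355, 135 and 367 genes against Col-0 in the order of the report, 75 for the combined mutant against pifq, 287 for it against ein3 eil1 and 156 for the interaction, with 19 lower in both, 9 higher in both and 9 lower in hls1 too. With genes listed at 0 left out, 40 genes lower in both were lower in hls1; the cause was not tested.

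The planned fits and their alternatives were not run: limma, camera with a preset or an estimated correlation, leaving out each sample, robust variance estimates, fits to the groups of 1 contrast, and replicate number as a block all need values per sample. No paired analysis was possible because the deposited table has no values per sample. Depth is unknown, so no limit from counting error is given.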

Other observations

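The tests of the phosphate starvation and the dehydration list were set before the values of those lists were seen, and both lists were chosen after the leading genes had been seen. Phosphate starvation genes were higher in both genotypes that lack the PIFs. Leaving aside PS2, PEPC1 and GDPD6, 15 of 16 listed genes were measured, and 11 were higher in pifq ein3 eil1 and 11 in pifq, with medians of 1.78 and 1.26. GDPD1, a glycerophosphodiester phosphodiesterase gene, stood at 74.7 RPKM against 13.7 in pifq ein3 eil1 and 44.4 in pifq, and the sulfolipid synthesis gene SQD2 at 40.0 RPKM against 10.4 and 26.5. The median in pifq ein3 eil1 lay at the 100 percentile of matched random lists, which is consistent with a wider phosphate starvation response as a hypothesis. No member passed the threshold in ein3 eil1, or 1 after median-of-ratios scaling, but 11 of the 15 were above 0. Their median there of 0.23, or 0.52 relative to all genes, also lay at the 100 percentile.

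For the dehydration and abscisic acid genes other than LEA7, RAB18 and LTI30, 7 of 12 listed were measured in ein3 eil1 and none passed the threshold. Their median of 0.19, or 0.48 relative to all genes, lay at the 99.3 percentile of matched random lists, so a wider dehydration response may be a small shift at most. In the same genotype, 3 of 4 measured seed storage and late embryogenesis genes were higher, with a list median of 1.61. The filter could keep these members through that genotype itself. A share of ungerminated seeds was not tested, so LEA7, RAB18 and LTI30 cannot be assigned to a dehydration response. In pifq, 5 of the 7 measured dehydration genes were lower, such as COR47 at 166 RPKM against 459 and ERD10 at 58.5 RPKM against 165.

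Plastid-encoded transcripts summed to 23505 RPKM in Col-0, 19913 in hls1, 23810 in pifq, 51886 in ein3 eil1 and 27143 in pifq ein3 eil1. Mitochondrial transcripts summed to 795, 778, 370.5, 2058 and 809.8 in the same order. A difference in the selection of polyadenylated RNA was not tested for either sum. The plastid gene ATCG01080, chosen after its values were seen, stood at 17.5, 86.5, 54.0, 417 and 52.0 RPKM.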
